A study of Mus musculus with 8 samples.

How the data were processed

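RNA was sequenced from outflow tracts of mouse hearts, the vessel segment that joins the ventricles to the great arteries, on a CD-1 background. Per the labels, 4 samples carried a knockout of Mef2c limited to the anterior heart field, a progenitor population that contributes to the outflow tract and right ventricle, and 4 samples were wild type. RNA was isolated with a Qiagen kit and the library kit came from NuGEN, per the labels' protocols. The stage, the number of embryos per sample and whether the samples came from separate litters are not given in the sources used here, so p-values measure the spread between these samples, which may in part be technical. Lane 1 held replicates 1 and 2 of each group and lane 2 held replicates 3 and 4.

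The authors deposited 1 table of 33495 Ensembl genes. Raw counts per gene and library were deposited by the authors as whole numbers. Reads were aligned with TopHat2 version 2.0.4 to the mm9 build, per the submitters' processing notes. The counting tool, its use of strand and the annotation release are not given in the sources used here. The table also held normalized log2 values per library, which were 0 in every library for 15221 genes and at least 5.79 otherwise. One pooled FPKM value per group, a modified log2 fold change, and scores that hold p-values and false discovery rates on a minus 10 log10 scale were made by the authors, per the file headers, with the USeq package. A further score from a chi-square test on exon counts and the log2 ratio of the exon with the largest change were deposited by the authors. The scale of the exon score is not stated in the header and was used only for ranking. Summed exon length per gene was also deposited and was not used. No read was reprocessed, and the number of columns of per-sample values left unmapped was 0.

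Total counts ran from 7138732 to 11012246 per library, so 3 counts, taken as the floor, equalled less than 1 CPM (counts scaled to library size) in each library. Intervals and floors cover counting error only, since the reads carried no molecular identifiers. Replicate pairs within a group differed beyond sampling noise, with a chi-square per degree of freedom of 5.77 to 20.67 over genes with at least 20 reads in the pair, so no library was a copy of another of its group.

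Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood test with robust dispersion, two-sided. P-values were adjusted by Benjamini-Hochberg over the 14757 genes tested, with a threshold of 0.05. The design held the group alone. The standard error of a log2 fold change was its size divided by the square root of F. CPM values used the TMM-scaled library sizes. The median log2 fold change of all tested genes was -0.006. Of the table's identifiers, 2198 shared a symbol with another, and a list member with several identifiers was taken as the one with most reads.

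Before the data were examined, 34 gene lists were fixed, and those with at least 5 tested members, 30 lists, were tested together with camera from limma 3.58.1 at a preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry. Members past 0.05 were counted with adjustment over all genes tested and adjusted over the list alone. Genes named in the text were chosen by a rule fixed at the same time. It took Mef2c and Tdgf1, and in each direction the 12 largest log2 fold changes among genes with an adjusted p under 0.05, a mean log2 CPM above 1 and no overlap between groups. It also took the 4 members with the smallest p of each list that passed its test or held 2 called members, the called member of other lists, and the most abundant member of cell type lists. This gave 82 genes, of which some are not reported here. Coordinates are those of the table on mm9, counted from 1.

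The procedure was tested on simulated data for the comparison of mutant with wild type, with 14757 genes. Of 50 genes changed at each size, it recovered 36% at 1.5-fold, 82% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 17 of the 183 calls (9.29%) were unchanged genes. A list shifted by -0.5 was found, and 0 of 30 random lists passed, but simulated genes varied independently, which genes in tissue do not.

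Alternatives fixed before the data were examined covered scaling, filtering, the test (DESeq2 1.42.0, limma-voom, limma-trend on the deposited normalized values, used as they stood because they were already on a log2 scale), a replicate block, lane, depth, and leaving out each library. Another 5 were added afterwards. Every split of the 8 samples into 4 and 4 was refitted, 35 in all. Comparisons of single values used exact permutation tests over all 70 arrangements, whose smallest two-sided p is 0.0286. Log2 CPM values per library used a prior count of 2. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.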

Results

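Gene expression was measured by RNA sequencing in outflow tracts of 4 mutant and 4 wild-type mouse hearts, in which the mutants lacked Mef2c in the anterior heart field. Total counts were 8880721, 7697492, 9963391 and 10006137 in mutant libraries 1 to 4 and 11012246, 7755888, 7423381 and 7138732 in wild-type libraries 1 to 4. Mutant library 1 and wild-type library 4 held almost no reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with 3 and 2 Ddx3y reads, while the other libraries held 419 to 596, so each group held 1 such library.

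The targeted gene was looked at first. Mef2c (ENSMUSG00000005583, chromosome 13, 83643194 to 83802927, plus strand, mm9) encodes a MADS-box transcription factor of muscle and heart development. Its gene-level count was 1390, 1150, 1227 and 1423 in the mutant libraries and 1207, 946, 791 and 728 in the wild-type libraries. It stood at 140.8 CPM ± 14.5 (SD, n = 4) in mutant and 112.6 ± 12.8 (SD, n = 4) in wild type, a log2 fold change of 0.32 ± 0.105 (SE) that did not pass (adjusted p = 0.212, edgeR), although it did with the chamber gene level as a covariate (adjusted p = 0.0338, edgeR). The gene-level count is not limited to the deleted part of the gene, so it does not check the labels. In the authors' deposited table Mef2c ranked 1 of all genes by the score of the exon test, and its most changed exon had a log2 ratio of -3.30 in mutant over wild type. Mef2a, a related factor, had a log2 fold change of 0.29 (adjusted p = 0.219, edgeR), and with adjustment over the list alone Mef2c and Mef2a, 2 of 3 tested MEF2 factors, were higher.

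The main comparison asked which transcripts differ in the outflow tract when Mef2c is lost from the anterior heart field. Mybpc1, a myosin-binding protein of skeletal muscle type (chromosome 10, 87981024 to 88067897, minus strand), fell from 61.7 CPM ± 16.9 to 0.815 ± 0.527 (SD, n = 4 each), and Lmod3, an actin filament nucleator of muscle, fell from 20.6 ± 4.51 to 3.09 ± 0.936 CPM. Tdgf1, the NODAL co-receptor also called Cripto (chromosome 9, 110818342 to 110848571, minus strand), had 9 reads over the 4 mutant libraries against 368 in wild type. Mstn, the muscle growth inhibitor myostatin (chromosome 1, 53118484 to 53124923, plus strand), rose most, from 1.83 ± 0.632 to 28.1 ± 5.94 CPM. In all, 222 of 14757 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 83 higher and 139 lower in mutant. Of these, 33 rose and 88 fell by more than 1 on the log2 scale.

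Of all tested genes 6.72% had no overlap between the groups, where chance gives 2.86%, and the 222 called genes, which the test selects for separated groups, all had none. The 222, called on both lanes together, went the same way in each lane, which their lack of overlap made all but certain. The Pearson r across these genes between the lanes' log2 fold changes was 0.890, a value that the same selection raises. Over all tested genes that r was only 0.128, and genes are not independent replicates. The test of group by lane had 2445 of 14757 genes at an unadjusted p under 0.05, more than the 5% that chance gives. After adjustment 1 passed, so many small differences between lanes, or between the samples on them, may remain. That gene was Lama2, a laminin chain, chosen after its values were seen, with an adjusted interaction p of 0.0309 by edgeR. With library size alone as scaling the calls split into 109 higher and 122 lower. The count fell to 112, 136 and 110 without mutant library 1, 2 or 3, to 145 without wild-type library 1 and to 95 without the 2 libraries lacking Y-linked reads, and rose to 430 with DESeq2 and 490 with the chamber gene level as a covariate. Lane 1 alone gave 836 and lane 2 alone 119, each with 2 libraries per group.

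**Figure D1:**
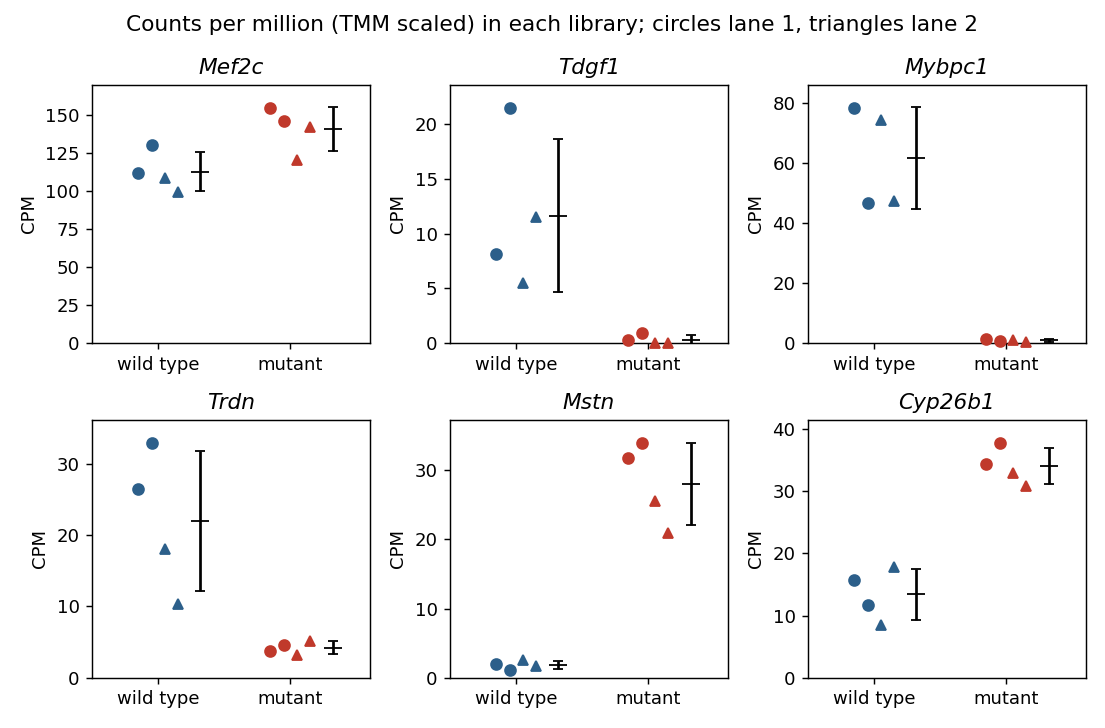
CPM (TMM scaled, linear axes from 0) of 6 genes in each library, wild type in blue and mutant in red, circles for lane 1 and triangles for lane 2, with the mean and SD of each group of 4 in black. Tdgf1, Mybpc1 and Trdn lay lower in every mutant library, Mstn and Cyp26b1 lay higher, and Mef2c overlapped.

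Among the largest falls, Tdgf1 changed by -5.47 ± 0.763 on the log2 scale (SE, adjusted p = 0.00724, edgeR). Its wild-type level was 46.4-fold that of mutant, with a 95% counting interval of 24.2 to 102. In lane 1 the ratio was 25.3, and in lane 2 the mutant libraries held 0 reads, so the level was at least 28.6-fold lower at a floor of 3 counts per library. Without the 2 libraries lacking Y-linked reads its call was lost at a value of -5.43 (adjusted p = 0.103, edgeR). The study itself singled out Tdgf1 on these samples, so its direction is not independent evidence. Efhd1, a mitochondrial calcium-binding protein, had 2 reads in mutant and 156 in wild type, a ratio of 88.6 with a counting interval of 24.1 to 738. Sgca, a sarcoglycan of the muscle membrane, fell by 3.50, and Mylpf and Myl1, light chains of fast skeletal myosin, fell by 3.10 and 2.78 on the log2 scale. Mylpf stood at -4.58 in lane 1 and -1.81 in lane 2, and the test of that difference did not pass (adjusted p = 0.0669, edgeR). Hpcal4, Ptprt, Arpp21 and Myo16 completed the 12 largest falls with Trdn and the genes above, at -3.12, -2.69, -2.63 and -2.36.

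Among the largest rises, Mstn changed by 3.92 ± 0.246 on the log2 scale (SE, adjusted p = 1.47e-05, edgeR). Sh2d4a rose by 2.39, the protease inhibitor Serpinb1a by 2.23, the keratin Krt80 by 2.03 and Nup62cl by 1.98. The water channels Aqp4 and Aqp1 rose by 1.71 and 1.33, from 9.91 ± 2.58 to 32.6 ± 2.88 CPM and from 7.63 ± 1.51 to 19.2 ± 2.30 CPM (SD, n = 4). The G protein subunit Gnal rose by 1.91, the phosphatase Dusp26 by 1.68 and Mab21l2 by 1.68. Gnal overlaps another gene on the same strand, and Mab21l2 lies within Lrba on the other strand, so part of their reads cannot be assigned with certainty.

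Some contractile genes fell. Of 32 tested sarcomere members 6 fell and 0 rose over all genes tested, and 12 fell when adjusted over the list alone. The myosin light chain Myl7 fell by 0.97 ± 0.134 (SE) on the log2 scale, from 1494 ± 245 to 765 ± 93.2 CPM (SD, n = 4), and the troponins Tnnt1 and Tnni3 fell by 1.36 and 0.94. Of the 5 most abundant members, picked after the values were seen, the myosin heavy chain Myh7 fell by 0.475 (adjusted p = 0.0325, edgeR). Titin (Ttn) at -0.433 passed only when adjusted over the list alone, and Actc1, Myh6 and Acta2 did not pass, at -0.06, -0.03 and -0.30. Ttn and Actc1 overlap genes on the other strand, and Myh6 and Myh7 are close paralogs, so part of their reads cannot be assigned with certainty. The list was lower by camera (adjusted p = 5.70e-14), but not with an estimated correlation (adjusted p = 0.300) or in lane 2 alone (adjusted p = 0.0759).

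Some calcium handling genes fell as well. Of 25 tested members 5 fell and 20 did not pass over all genes tested, 6 fell when adjusted over the list alone, and the list's median was -0.156. Triadin (Trdn) fell by 2.40, from 21.9 ± 9.80 to 4.17 ± 0.900 CPM, and the calcium store protein Casq2 fell by 2.34, from 34.3 ± 8.20 to 6.80 ± 1.65 CPM (SD, n = 4). Hrc, the histidine-rich calcium-binding protein, fell by 0.88, and the calcium channel Cacna1c fell by 0.54, although it overlaps Dcp1b on the other strand. The list passed camera (adjusted p = 1.07e-07) and not the test with an estimated correlation (adjusted p = 0.304). Of the genes reported as MEF2 targets, 4 of 17 fell, and 7 when adjusted over the list alone. The 4 were Lmod3 at -2.73, Hdac9, a histone deacetylase, at -1.03, Hrc and Tdgf1. Hrc and several other members also belong to the sarcomere, calcium or muscle energy lists, so this list is not evidence separate from those. This list passed camera (adjusted p = 3.28e-10; 6.17e-08 without Tdgf1, which the study chose on these samples) and not with an estimated correlation (adjusted p = 0.243).

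**Figure D2:**
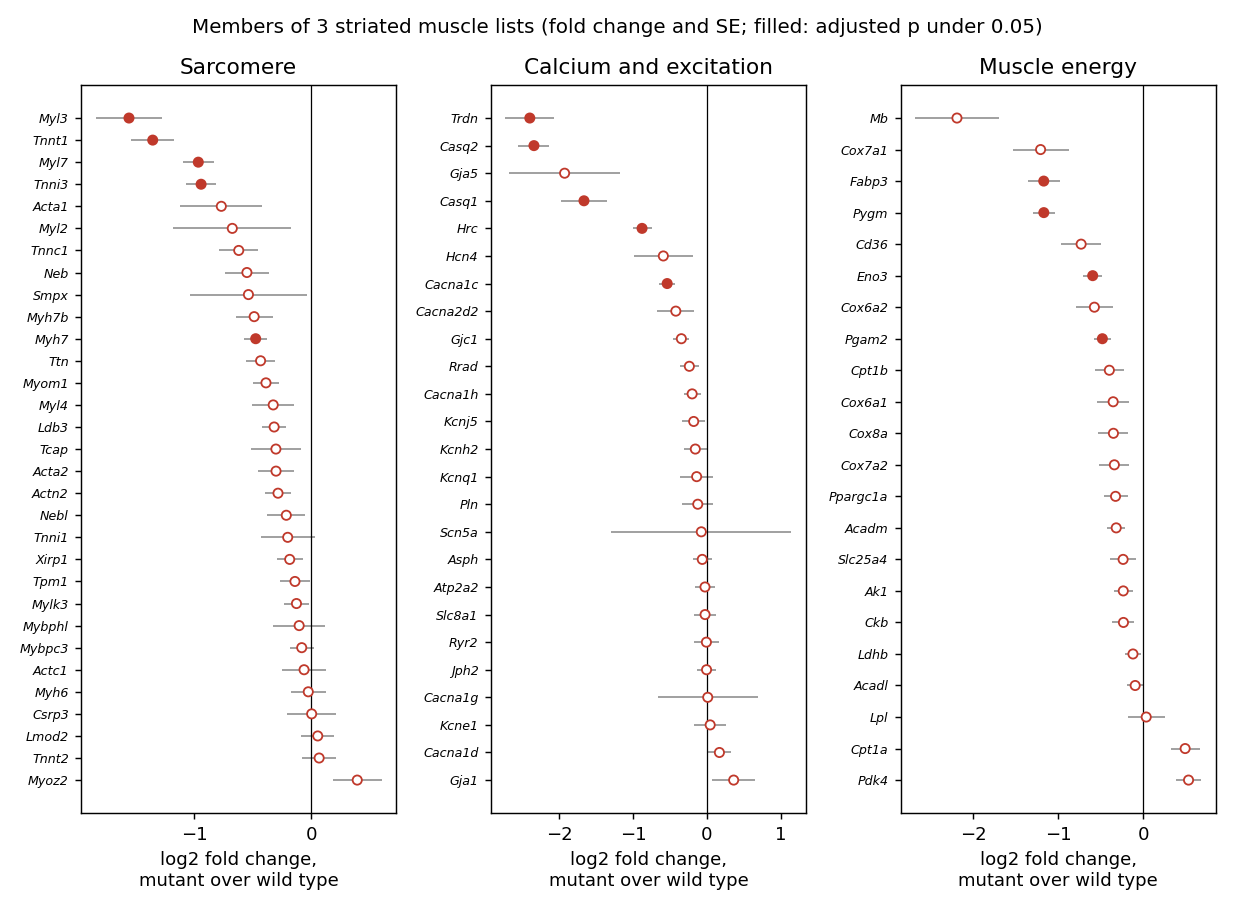
Log2 fold change of mutant over wild type with its SE for 31 of 32 tested sarcomere members, 25 of 25 calcium members and 22 of 22 muscle energy members, filled where the adjusted p was under 0.05. Most members lie left of 0, and 5, 5 and 4 of those drawn are filled.

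Some energy genes of muscle fell too. Of 22 tested members 4 fell and 18 did not pass over all genes tested, and 9 fell and 2 rose when adjusted over the list alone. The glycogen phosphorylase Pygm fell by 1.17, the fatty acid binding protein Fabp3 by 1.17, the enolase Eno3 by 0.59 and the phosphoglycerate mutase Pgam2 by 0.48 on the log2 scale. Fabp3 overlaps Zcchc17 on the other strand. The list passed camera (adjusted p = 3.54e-10), but not with an estimated correlation (adjusted p = 0.300) or in lane 2 alone (adjusted p = 0.191). Mitochondrially encoded transcripts took 5.54% ± 0.415 of the reads in mutant and 6.74% ± 0.367 in wild type (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest these arrangements allow). That share was not among the comparisons fixed before the data were examined. All 38 tested features of that chromosome had values below 0, and 2 of them were called. Such features make up the share, so their common direction restates its difference.

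Lists of signalling and neighbouring tissues held few called genes. The retinoic acid enzymes Cyp26b1 and Aldh1a2 rose by 1.33 and 1.25, 2 of 15 tested members, while the list's median was -0.147, its mean 0.181 and its camera direction higher (adjusted p = 0.0341, and 0.479 with an estimated correlation). That direction turned in lane 2 alone (adjusted p = 0.671), and the call was lost without mutant library 3 or 4 (0.101 and 0.0744) or wild-type library 1, 2 or 3 (0.0546, 0.506 and 0.0561). Aldh1a2 was also the 1 called epicardial gene of 9, with Tcf21 at 0.70 and Upk3b at 0.47 not called, and the epicardial list was higher (adjusted p = 2.03e-04, 0.370 with an estimated correlation and 0.687 in lane 1 alone). Of 27 Wnt genes, the inhibitor Apcdd1 rose by 1.10, and the list was higher (adjusted p = 4.00e-04, 0.300 with an estimated correlation and 0.622 in lane 2 alone). The collagen Col2a1 fell by 1.74, from 341.2 ± 53.1 to 102.5 ± 9.69 CPM (SD, n = 4), in a cushion and matrix list whose direction by camera was higher (adjusted p = 0.0148, 0.623 with an estimated correlation, 0.803 in lane 2 alone, and 0.294 and 0.0629 without wild-type library 2 or 4). In the stress list Atf3 rose by 1.22 (list adjusted p = 0.00276, 0.300 with an estimated correlation and 0.197 in lane 2 alone). In the hypoxia and glycolysis list the glucose transporter Slc2a3 fell by 1.12 (list adjusted p = 0.0162, and 0.629 with an estimated correlation). That list, lower by camera, turned direction in lane 2 alone (adjusted p = 0.603) and was lost without mutant library 2 or 3 (0.0941 and 0.181) or wild-type library 1 (0.589). In the NODAL list Tdgf1 was the 1 called member of 8 (list adjusted p = 0.0231, 0.478 with an estimated correlation, 0.357 in lane 1 alone, and 0.108 and 0.208 without mutant or wild-type library 4). The study chose Tdgf1 on these samples, and without it, an alternative added after the data were seen, the list did not pass (adjusted p = 0.386, camera). Liver and yolk sac genes had 0 called members of 6, and 5 were higher when adjusted over the list alone, led by Apob at 2.44 and Afp at 3.20 (list adjusted p = 6.53e-07, and 0.300 with an estimated correlation).

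In all, 12 of 30 lists passed camera, 6 lower and 6 higher, and 0 passed with an estimated correlation or by fry's directional test, where 3 and 10 lists had an unadjusted p under 0.05. By fry's mixed test, which asks whether members change in either direction and does not compare a list with other genes, 21 of the 30 passed. The count of lists did not stand apart from regrouped samples, since 11 of the 35 splits of the 8 libraries gave 12 or more. By single list, the real grouping gave the smallest p of the 35 splits for the sarcomere, calcium and reported MEF2 target lists. The unadjusted camera p was 1.90e-15 for sarcomere, 1.43e-08 for calcium and 2.19e-11 for reported MEF2 targets. The smallest of any other split was 7.62e-13, 1.17e-07 and 1.58e-05, so a very small camera p alone does not mark the real grouping. The muscle energy and Wnt lists were matched by 1 other split each. Stress and hepatic lists were matched by 2 others each, NODAL by 3, epicardium by 4, retinoic acid by 8, cushion and matrix by 18 and hypoxia by 19. These shares are not adjusted, since 35 splits are too few for an adjustment over 30 lists.

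Second heart field genes did not shift as a list, with 0 of 23 called and an adjusted p of 0.334 by camera. When adjusted over that list alone 3 members were lower, among them Tbx3 at -1.03 and Smyd1 at -0.51, named after their values were seen. Smooth muscle, cell cycle, FGF, Hedgehog, chamber myocardium, pharyngeal, branchiomeric, erythroid and leukocyte lists had 0 called members and did not pass. The remaining lists that did not pass held 1 or 2 called genes. Tek, an endothelial receptor, rose by 0.74, Msx1 by 1.06 and the imprinted receptor Igf2r by 0.52, while Sema3a fell by 0.72 and the Notch ligand Jag2 by 1.06. In the list of p53 targets Plk2 rose by 0.76 and Perp fell by 2.00. Igf2r overlaps an antisense gene. The most abundant markers of other cell types did not pass, with Cdh5 of endothelium at 0.10, Sox9 of neural crest at 0.29, Krt19 of epithelium at -0.27, Tubb3 of neurons at -0.24, Laptm5 of leukocytes at -0.98, the embryonic globin Hba-x at -0.45 and Meox1 of somitic muscle precursors at -0.18. Sox9 also belonged to the cushion and matrix list and Krt19 to the epicardial list, so neither is specific to the cell type named. Tubb3 overlaps Usp10, which had more reads, and Meox1 overlaps another gene, each on the same strand, so part of their reads cannot be assigned with certainty.

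Libraries also differed within groups in chamber genes, such as natriuretic peptides and ventricular light chain. The median centred log2 CPM of that list was highest in wild-type library 2, at 1.19, and mutant library 4, at 0.832, and lowest in mutant library 3. Without these 2 libraries, an alternative chosen after the data were seen, 296 genes changed, 120 higher and 176 lower, and 184 of the 222 calls remained. Wild-type library 2 was on lane 1 and mutant library 4 on lane 2. The chamber list was lower in mutant in lane 1 alone (adjusted p = 6.25e-07, camera) and higher in lane 2 alone (adjusted p = 0.00316, camera). Results of single lanes therefore cannot be told apart from the effect of these 2 libraries. Other lists varied within groups too. Erythroid genes varied more widely, from -1.642 to 0.937 in the mutant libraries and from -0.689 to 1.595 in the wild-type libraries.

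**Figure D3:**
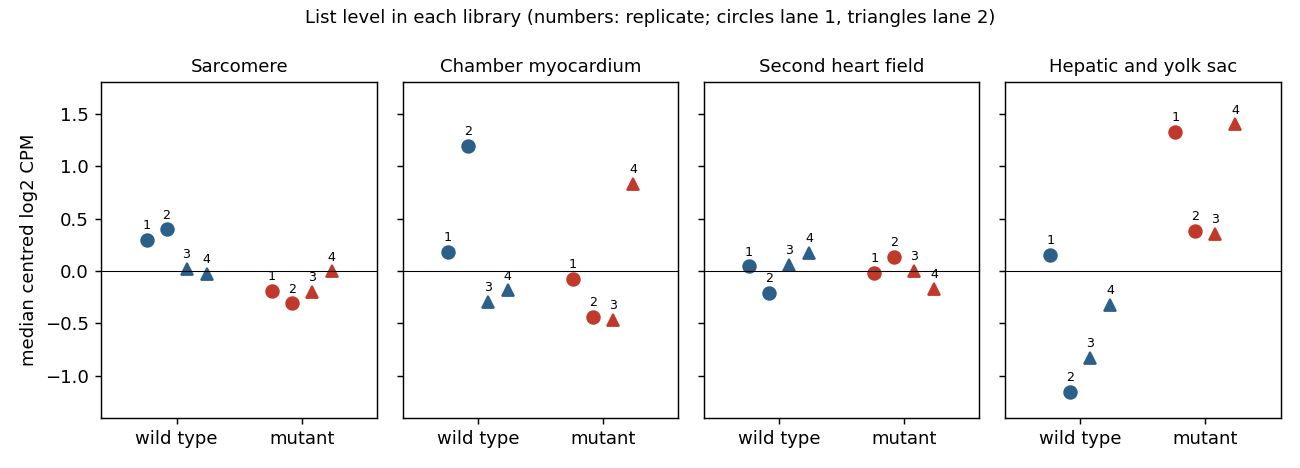
Median centred log2 CPM of 4 gene lists in each library, wild type in blue and mutant in red, numbered by replicate, circles for lane 1 and triangles for lane 2. Chamber genes were highest in wild-type library 2 and mutant library 4, and the liver and yolk sac level lay higher in each mutant library than in any wild-type library.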

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

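The tests of sample splits for the gene and list counts were fixed before any split was fitted, and all other tests in this part were chosen after the results were seen.

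Each of the 82 named genes and the 4 Y-linked genes was searched, in each group of 4, for 1 library far from the others. Of 172 groups, 12 had such a library, and chance gives about 5%. Of these, 8 were Y-linked and restate the missing reads given above. The other flags were not more than chance gives. In mutant library 1, log2 CPM was -0.57 for Eif2s3y, -1.56 for Kdm5d, -1.56 for Uty and -0.83 for Ddx3y. In wild-type library 4 it was -1.46 for Eif2s3y, -2.13 for Kdm5d, -2.13 for Uty and -1.01 for Ddx3y. In the other libraries these genes lay above 5. Tek was highest in wild-type library 3, at 6.79 against 6.61 to 6.64. Aqp1 was lowest in wild-type library 2, at 2.47 against 3.07 to 3.13. Wnt9b was highest in mutant library 1, at 3.56 against 2.82 to 2.92. Axin2 was highest in mutant library 3, at 5 against 4.69 to 4.74.

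The gene counts were set against all 35 splits of the 8 samples. Only 1 split, the real one, gave 222 changed genes, 83 higher genes or 139 lower genes, and no other split called more than 1 gene. A share of 1 in 35 is the smallest these samples allow. The other splits mix mutant and wild type, which adds any group difference to the spread and lowers their counts. The real grouping thus stands apart, but chance is not excluded by these counts. For lists the real grouping did not stand apart, since 11 splits gave 12 lists or more and the highest other split gave 18.

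Some striated muscle genes were lower in mutant, with 15 members of the sarcomere, calcium and muscle energy lists called. A lower share of cardiomyocytes was weighed as the whole cause. The 10 most abundant sarcomere genes changed by a mean of -0.278 on the log2 scale. The median for called members was -1.16 (exact permutation p of that shift = 0.0286). The called members were selected for clear falls in the same data, so a smaller mean fall in the abundant genes was likely in advance. That p therefore does not decide the question. Fewer cardiomyocytes alone would lower genes restricted to them by about the same amount. Within the 10, picked by abundance, values ran from -0.966 ± 0.134 for Myl7 to 0.068 ± 0.146 for Tnnt2 (SE). Actc1 and Myh6 stood at -0.061 ± 0.187 and -0.025 ± 0.148. These unequal values argue against a lower share as the whole cause for these genes, but not as a part of it. A small common fall from fewer cardiomyocytes cannot be told apart from no change. The mean over the 10 genes gave an exact permutation p of 0.143, while 9 of the 10 lay below 0. All 15 stayed called with the chamber gene level in the model, but so did 219 of the 222 calls. The calls thus did not depend on that covariate, but staying called was the rule for any called gene. The fit therefore does not decide whether uneven chamber tissue contributed. Loss of Mef2c in the anterior heart field, the difference the design names, stays open as a hypothesis. The fall could not be told apart from other changes in tissue makeup.

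The liver and yolk sac list was higher in mutant by camera (adjusted p = 6.53e-07, and 0.300 with an estimated correlation), with 0 of 6 tested members called by edgeR over all genes and 5 higher when adjusted over the list alone. Carry-over of such tissue is a candidate explanation. With group means removed, Afp went with the other 15 list members summed at a Pearson r of 0.386 (permutation within groups p = 0.481; Spearman rho 0.7, p = 0.111; r = 0.609 without the 2 farthest libraries), which leaves it open. An earlier test gave a summed level of 45.9 ± 13.2 CPM in mutant and 19.6 ± 7.22 in wild type (SD, n = 4; exact permutation p = 0.0286), but it used members of the list that made the call and so restated the pattern. Alb, an abundant liver transcript, had 3 reads in all, and the studied tissue may also express Trf, Rbp4 and Cubn. For this list 3 of the 35 splits gave a set test p as small, the smallest other being 2.568e-14, so a chance arrangement of the samples cannot be excluded.

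Chamber genes varied within groups, with a range of 1.48 in mutant and 1.57 in wild type on the log2 scale. Here the chamber and second heart field levels leave out Hand1, which both lists hold, so they differ from the levels given above. Uneven amounts of chamber in the dissections may account for it, since the level fell as that of second heart field genes rose (Pearson r = -0.815, permutation p = 0.0162; Spearman rho = -0.667, p = 0.0831). The relation rests on wild-type library 2 and mutant library 4, without which r was -0.207 (permutation p = 0.678). It was -0.885 and -0.797 in lanes 1 and 2, with 4 libraries each, but each lane held 1 of these 2 libraries. Depth is argued against, since 99.3% of the range remained after thinning to equal totals. Lane is argued against, since lane means differed by 0.275 and the range within each lane was at least 1.48.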

How the results depend on the processing

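The chamber covariate, the fits without the chamber-rich libraries, without mitochondrial and rRNA features and without the libraries lacking Y-linked reads, and lists without Tdgf1, were chosen after the data were seen, and other settings were fixed before. Those of the 222 calls that were tested kept their direction in every setting run. For fits on fewer libraries this was all but fixed, since none of these genes overlapped between groups. How many passed depended on the setting, and the cause was not tested unless stated. DESeq2 gave 430 changed genes (186 higher, 244 lower), which included all 222. Lane 1 alone, with fewer samples, gave 836 (234 higher, 602 lower), and lane 2 alone gave 119 (41 higher, 78 lower). Leaving out 1 library gave 110 to 231 changed genes, 28 to 82 higher and 77 to 149 lower, lowest without mutant library 3 or 1, with Mef2c at 0.27 to 0.39, Tdgf1 at -7.13 to -5.01 and 12 to 14 lists. Same-numbered samples did not deviate together (correlations -0.05, -0.212, 0.222 and -0.287), so the numbers were not taken as pairs, and the replicate block gave 76 changed genes (22 higher, 54 lower). Library size alone gave 231 genes, 47.2% of them higher against 37.4% in the main test. The chamber level as a covariate gave 490 (212 higher, 278 lower), kept 219 of the 222, and took Mef2c past the threshold at 0.37 (adjusted p = 0.0338, edgeR). Without the 2 libraries lacking Y-linked reads 95 changed (24 higher, 71 lower), and Tdgf1 stood at -5.43 with an adjusted p of 0.103 by edgeR, with fewer samples.  The test of group by lane called 1 gene, and a comparison of separately fitted lanes, each of 2 against 2, called 1042. Signs turned for named genes that were not called. Cdh5 ran from -0.01 to 0.17 with 1 library left out, and was at -0.05 in lane 2. Hba-x ran from -0.85 to 0.11 and was at 0.08 in lane 1. Meox1 ran from -0.49 to 0.25 and was at 0.42 in lane 1, 0.05 with limma-voom and 0.02 with limma-trend. Tbx18 and Aldh1a1 were at -0.02 in lane 1. Other scalings and filters, and limma-voom and limma-trend, gave 212 to 274 genes, and lane as covariate 170. Thinning to the smallest library gave 219 genes and kept 200 of the 222, so this loss of depth moved the count little. At these depths 36% of simulated 1.5-fold changes, in genes with a mean above 2 CPM, were recovered, and depth was not varied in the simulation.

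For the gene lists, values are adjusted p by camera. With an estimated correlation 0 of the 12 lists stayed past the threshold, at 0.300 for sarcomere, Wnt, hepatic, stress and muscle energy genes, 0.304 for calcium, 0.243 for reported MEF2 targets, 0.370 for epicardium, 0.478 for NODAL, 0.479 for retinoic acid, 0.623 for cushion and matrix and 0.629 for hypoxia. Lane 1 alone ended the calls of NODAL (0.357) and epicardium (0.687) and added chamber (6.25e-07) and Hedgehog (2.71e-05). Lane 2 alone ended those of sarcomere (0.0759), Wnt (0.622), cushion and matrix (0.803), stress (0.197) and muscle energy (0.191). It turned the direction of chamber (0.00316), retinoic acid (0.671) and hypoxia (0.603). It added second heart field (0.00316), Notch (3.41e-07), semaphorin (4.99e-04), pharyngeal (0.00506), branchiomeric (0.0330), erythroid (0.00467), leukocyte (5.79e-09) and cell cycle (0.0184). Retinoic acid was lost with library size only (0.0692), no filter (0.113), limma-voom (0.111), the chamber covariate (0.167) and without the chamber-rich libraries (0.405). NODAL was lost with no filter (0.255), limma-voom (0.0831) and without the libraries lacking Y-linked reads (0.230). Without Tdgf1 11 lists passed, NODAL was lost (0.386) and reported MEF2 targets stayed (6.17e-08). The libraries lacking Y-linked reads left out also ended cushion and matrix (0.0889) and added Hedgehog (0.00558) and endothelium (0.00619), and the chamber covariate ended hypoxia (0.0843) and added Notch (0.0153). Leaving out the chamber-rich libraries added chamber (0.00575), Notch (0.01003), branchiomeric (0.0406) and leukocyte (0.0321). No filter added endothelium (0.0474), pharyngeal (0.0211) and leukocyte (0.0444), and the stricter filter added branchiomeric (0.0353). The replicate block added Notch (0.0401), erythroid (0.00547) and leukocyte (0.00881), and lane as covariate added leukocyte (0.0148). With 1 library left out, values ran from 0.00283 to 0.208 for NODAL, 6.29e-04 to 0.506 for retinoic acid, 3.45e-04 to 0.294 for cushion and matrix, 1.79e-04 to 0.589 for hypoxia, 0.00975 to 0.399 for branchiomeric, 0.00437 to 0.910 for chamber, 0.0237 to 0.352 for endothelium, 0.00948 to 0.878 for erythroid, 8.50e-04 to 0.506 for Hedgehog, 2.94e-04 to 0.460 for leukocyte and 0.00453 to 0.430 for Notch genes. The sarcomere, calcium, reported MEF2 target, muscle energy, hepatic, epicardial, Wnt and stress lists stayed past the threshold with any 1 library left out.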

Other observations

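No test was run for this part, and the genes were picked by rank after their values were seen. In the authors' deposited table, some genes stood among the 20 highest scores of the exon test while their gene-level values in the same table lay near 0. These values are the modified log2 fold change of USeq, which need not follow the pooled FPKM of that table. Syne1 stood at 6.22 FPKM in mutant and 7.49 in wild type, and Tpm3 at 52.4 and 41.1, so a value near 0 does not show an equal level. Mef2c came first and Syne1, which encodes the nuclear envelope protein nesprin-1, second, with a most changed exon at -2.44 and a gene-level value of 0.11. Mtus1 had an exon at -2.85 and a gene-level value of 0.07. Tpm3, a tropomyosin, had an exon at -2.85 and a gene-level value of 0.03, and Capzb, an actin capping protein subunit, had an exon at -2.64 and a gene-level value of 0.01. Other genes of the 20 had a most changed exon that was higher in mutant, such as Myo10 at 1.92 and Vps8 at 2.05. The table gives no replicate values for exons.

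The authors' deposited table called 579 genes at a false discovery rate of 0.05, 266 higher, 299 lower and 14 at 0 by its modified log2 fold change. By its pooled FPKM 209 of them were higher and 370 lower, and 120 had opposite signs on the 2 scales. Of the 579, 534 were tested here and 211 were among the 222 calls, all 211 in the same direction on both scales.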
